A study of Mus musculus with 37 samples.

How the data were processed

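RNA from the lungs of female C57BL/6 mice, an inbred laboratory strain, was measured on 37 two-colour Agilent gene expression arrays. The mice had received 0, 54, 162 or 486 µg of anatase titanium dioxide nanoparticles (diameter 20 nm), a white pigment material, in 40 µl of liquid instilled once into the trachea, and the lungs were taken at day 1 or day 28. The groups held 4, 5, 5 and 4 arrays at day 1 and 5, 5, 4 and 5 at day 28 in order of dose. The dose of 18 µg and the collection at day 90, which the design text also names, were not analysed here. Per the labels' protocols, 200 ng of lung RNA from randomly taken tissue sections was labelled with Cy5 and universal mouse reference RNA, a pool from 11 mouse cell lines, with Cy3. The labels give 5 sections per group without saying that each came from another mouse, so p-values measure the spread between these samples. Dyes were not swapped, and every ratio was read as lung over reference. Group, day and dose came from the sample labels, and replicate numbers follow deposit order. No label says that a number marks a shared animal or batch, but most same-numbered arrays of a day lay on the same slide.

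The scanner files hold the intensity of each spot and of its local background in both dyes as the authors' scanner software, Agilent Feature Extraction 11.0.1.1, wrote it, per the file headers, with no correction applied. The submitters' processing notes name the same software without a version. The log10 ratio of Cy5 over Cy3 in those files was already background-subtracted and dye-normalized by that software, per the file headers. The deposited series table holds values that behave as log2 ratios of Cy5 over Cy3. Its direction and scale were found by setting each column against its array, where it correlated with the ratios computed here at 0.975 to 0.998 across probes, with slopes of 0.715 to 0.990 against the scanner values. Its column medians lay between -0.049 and -0.025. What background correction and normalization the authors applied to that table stays unknown, including whether columns were centred on another set of probes. The files hold median and no mean spot signals, so the median signals were used where the mean had been planned. Probe annotation in the files is on build mm9 and the gene table used for names is on another assembly, GRCm38.p6, so no coordinates are given.

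Spots carrying an outlier mark in either dye (4551, 0.284% of the spots that are not controls) were left out, saturated spots were kept, and 0 Cy5 spots of tested probes were saturated. Background was corrected with normexp (offset 50) and ratios were normalized by loess within each array with control spots at weight 0, in limma 3.58.1 under R 4.3.3, with statmod 1.5.0. The offset draws ratios of dim spots towards 0, so changes of dim genes are understated. The 43379 spots that are not controls made 41174 probes, 245 of them spotted 10 times and averaged. Probes were named by matching their unversioned accession to the gene table, which gave 1 symbol to 27479 probes (18749 symbols), and 13695 probes kept the name in the files. The 28353 probes well above background in Cy5 on at least 4 arrays were kept, and the probe with the highest mean intensity stood for each gene. That left 21344 genes, 14979 of them with a symbol and 6365 without. Other probes of a gene were used only to see whether they moved the same way. Among named genes they moved apart for Sema3e (2 of 3 probes with the same sign), Cxcl12, Adgre1 and Retnla (1 of 2 each) at day 1. The same held for Col3a1 (1 of 2 probes) at day 1. Some of the genes looked at are not reported here.

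A limma model with 1 mean for each of the 8 groups was fitted to the log2 ratios of all 37 arrays, and 10 contrasts were tested with moderated statistics, two-sided, with Benjamini-Hochberg adjustment and a threshold of adjusted p 0.05. They were each dose against 0 µg at each day, 486 against 162 µg at each day, and the difference between days of the 162 and 486 µg effects. Each of 40 gene lists was tested in each contrast with limma's camera on preranked statistics, with a preset correlation of 0.01 and then with the correlation estimated from the data, adjusted over the lists within a contrast. The estimate used all 37 arrays in every contrast and was not repeated with arrays left out. Genes named here followed a rule. It took the 8 largest changes each way past the threshold at 486 µg (4 in other contrasts) with every array on 1 side of the control mean, passing over clone and predicted names. It added a panel of 33 genes, and, for each list described, up to 4 members with the smallest adjusted p and up to 2 that did not pass. The groups, contrasts, lists, panel, rule and most alternatives were fixed before the data were examined. The panel genes Ccl22 and Mmp12 were not tested, since their probes were well above background on at most 0 and 3 of the 4 arrays needed.

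The alternatives fixed in advance were no background correction, the scanner software's ratio, the series table, Cy5 alone after quantile normalization, scaling and intensity quantiles between arrays, no filter on dim probes, and a filter on both dyes. Others were slide as a fixed or random block, scan day as a block, a model of only the groups compared, array weights, an intensity trend with a robust prior, every probe or the mean of a gene's probes, a fold of at least 1.5, and leaving out each array in turn. The 5 settings that limit the local background or leave out doubted arrays, and a block of replicate number, were chosen after seeing the data, and are named as such where they are used. The model was tested on simulated data of 21135 genes with 100 genes changed by 1 and 100 by 2 on the log2 scale. For 486 against 0 µg it recovered 92% and 100% of these at day 1, with 10 false calls, and 95% and 100% at day 28, with 14 false calls. At 54 µg it recovered 94% and 100% at day 1 (12 false calls) and 96% and 100% at day 28 (10 false calls). At 162 µg it recovered 95% and 98% at day 1 (6 false calls) and 93% and 100% at day 28 (8 false calls). Noise in the simulated data was drawn independently for each gene and array, with no slide effect, no outlying array and no correlation between genes. These shares therefore do not carry over to the real arrays. At 162 µg on day 1, Saa3 was 3.74 higher and was not called.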

Results

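Gene expression was measured on 37 arrays of lung RNA from female mice taken 1 day or 28 days after a single dose of 0, 54, 162 or 486 µg of titanium dioxide nanoparticles. The groups held 4, 5, 5 and 4 arrays at day 1 and 5, 5, 4 and 5 arrays at day 28. The study asked how the lung transcriptome answers to particle dose and time, with fibrosis-like change at high dose as its stated interest. Each value is the log2 ratio of lung RNA to a common reference, so a group difference of 1 is a doubling. Between 56.7% and 69.6% of probes were well above background in the lung dye on an array, and the median lung signal stood 1.46 to 2.15 times above local background. The 37 arrays lay on 10 slides, each slide holding 1 day and up to 1 array of every dose, and were scanned on 4 days. Pairs of arrays correlated at 0.882 to 0.988 over all genes. The 4 day 1 arrays of slide 5 departed from the other arrays of their groups in acute phase genes, by 1.04, 0.61, -1.56 and -1.57 from 0 to 486 µg, where the median SD of the others was 0.273. The acute phase gene Saa3 was at 1.77 on the array labelled 0 µg there, against -3.70 to -3.27 on the other 3 control arrays. It was at -4.00 on the slide's 162 µg array, against 2.30 to 3.71 on the other 4. Values without the 4 arrays of slide 5, a choice made after seeing the data, are given for day 1 where the call of a named gene changed, and as counts for most lists. Since these arrays were chosen by their values, counts without them are no independent test of the dose.

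One day after 486 µg, 310 genes passed the threshold against control lungs as designed, against 0 to 2 in the other 9 comparisons. That count was 0 with slide as a fixed block and fell to a few genes with the local background limited. Set directly against 162 µg at day 1, 486 µg gave 0 genes, so the counts alone show no difference between these doses. The metallothionein Mt2, a metal-binding protein, rose by 2.85 ± 0.691 on the log2 scale (SE, 4 against 4 arrays, limma adjusted p = 0.0396), a 7.22-fold difference, but came to 1.37 under scaling to equal spread and lost its call in 17 of 28 other settings. Angptl4, a secreted inhibitor of lipoprotein lipase, rose 4.40-fold (log2 change 2.14 ± 0.524), with the call lost in 15 of 28 other settings. The matrix glycoprotein Tnc rose 3.04-fold. The apelin receptor Aplnr, an endothelial gene, fell 3.03-fold (log2 change -1.60 ± 0.397), with the call lost in 15 of 27 other settings. The interferon-induced GTPases Gbp6 and Gbp2 fell by 1.21 and 0.89, although Gbp2 was at 0.04 when array ratios were scaled to equal spread. Such scaling divides by each array's spread, which the background fit had narrowed on slide 5's 486 µg array, as given further below.

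In that comparison limma called 310 of 21344 genes, 119 higher and 191 lower, of which 75 and 134 changed at least 1.5-fold, with a lowest adjusted p of 0.0299. At an unadjusted p of 0.05 the count was 4021, 18.8% of genes, where chance gives about 5%. The arrays of the 2 groups did not overlap for 1742 genes, 8.22% against the 2.86% that chance gives. The number of calls hung on single arrays and on the treatment of background. With slide as a fixed block no gene passed, and with slide as a random block 705 did (262 higher, 443 lower). Under other scalings of the arrays the split moved. Scaling to equal spread gave 6 higher and 4 lower, the lung dye alone 46 and 39, the values of the series table gave 5 and 0, and no background correction 4 and 1. Limiting the local background of 39 spots, which was chosen after seeing the data, left 5 genes, all among the 310. A lost call need not mean a lost change. Over all settings, this one included, Angptl4 stayed at 1.87 or more, whereas Ak7 came to -0.26 at the least. Without the 4 arrays of slide 5 limma called 1998 genes, 1174 higher and 824 lower, 302 of them among the 310. Leaving out single arrays gave 0 calls without 0 µg replicate 3 or 4 or 486 µg replicate 1, 3 or 4, 98 and 141 without 0 µg replicates 1 and 2, and 1613 without 486 µg replicate 2.

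**Figure D1:**
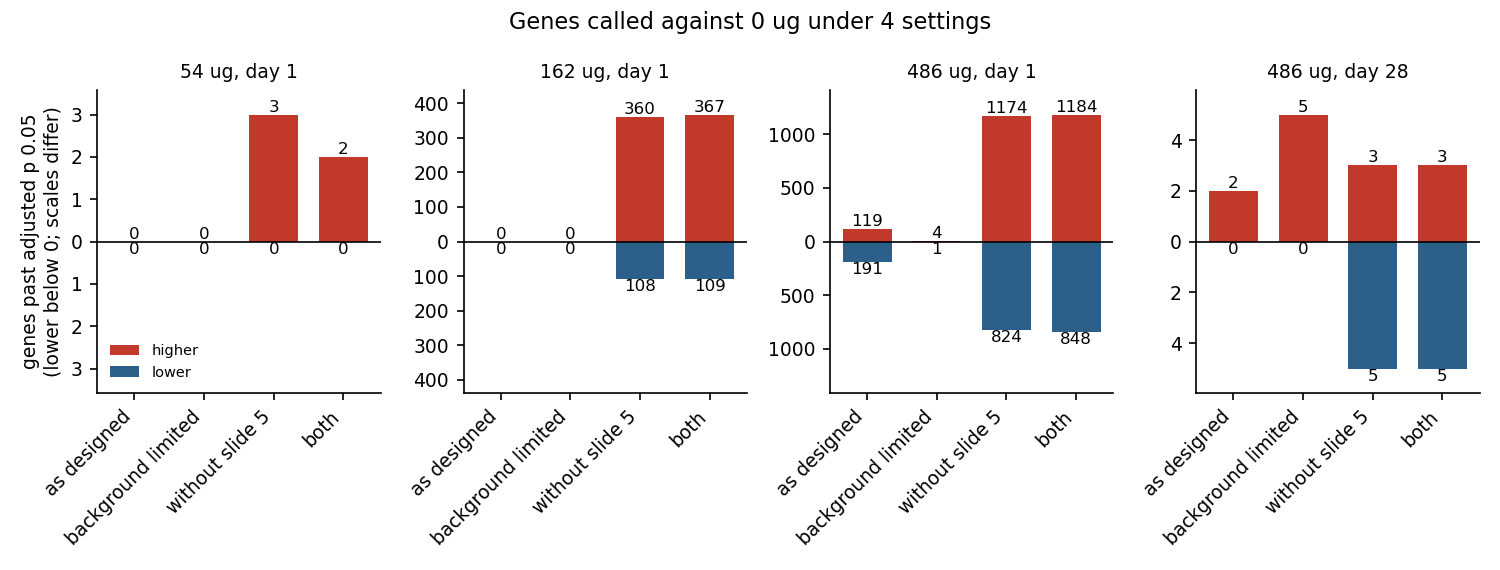
Number of genes past limma's adjusted p of 0.05, higher above and lower below the zero line, for 54, 162 and 486 µg against 0 µg at day 1 and 486 µg at day 28, under 4 settings. For 486 µg at day 1 the bars read 119 higher and 191 lower as designed, 4 and 1 with the background limited, 1174 and 824 without slide 5, and 1184 and 848 with both.

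The largest increases past the threshold at 486 µg on day 1, among genes with every 486 µg array above the control mean, included Angptl4, Pla1a, Map3k6, Tnc, Pmvk, Ankrd1 and Rgcc. Pla1a, a phospholipase of the cell surface, stood at 1.09 ± 1.1 (SD, n = 4) against -0.79 ± 0.484 in controls. Map3k6, a stress kinase, rose by 1.78, Pmvk, an enzyme of the mevalonate pathway, by 1.59, and Ankrd1, a nuclear cofactor of muscle and injured tissue, by 1.58. Rgcc, a regulator of the cell cycle, stood at 5.46 ± 0.860 against 4.07 ± 0.179. On the 3 slides that held both groups, Angptl4 differed by -0.21 to 3.29, and the lowest difference of each of these 7 genes, -0.21 to 0.18, was that of slide 5. The largest decreases, by the same rule, were Aplnr, Ak7, Bcan, Mamdc2, Clec3b, Ms4a4b, Tinag and Gbp6. Ak7, an adenylate kinase of cilia, fell by 1.40 and stood at 2.67 ± 0.296 against 4.08 ± 0.802. Bcan, a proteoglycan, fell by 1.40, Mamdc2 by 1.30, Clec3b, which encodes tetranectin, by 1.27, Ms4a4b, a membrane protein of T cells, by 1.25, and Tinag by 1.24. All 8 were lower on 3 of 3 slides. The naming rule favours this, since it asked every 486 µg array to lie below the control mean. These 8 genes stayed negative under every other setting, but Ak7 came to -0.26, Mamdc2 to -0.13, Tinag to -0.20, Ms4a4b to -0.42 and Clec3b to -0.55 at the least. The 7 increases stayed at 1.03 or more. Calls were still lost in many settings, in 18 of 28 for Ankrd1, 16 of 28 for Ak7 and for Clec3b, and 15 of 28 for Bcan.

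Acute phase genes, made by liver and by inflamed lung, led the inflammatory response by size while most missed the threshold. Of 17 measured, 2 rose over all genes tested, Orm1 (1.49 ± 0.366, adjusted p = 0.0396) and Il6 (0.84 ± 0.222, adjusted p = 0.0476), and 10 when adjusted over the list alone. Il6 was well above background on 3 of 4 dosed and 1 of 4 control arrays, and Orm1 on 4 and 2. Saa3 was 4.40 ± 1.20 above controls (21.1-fold, adjusted p = 0.0511), with 2.21 ± 1.95 (SD, n = 4) at 486 µg against -2.19 ± 2.65 in controls, and Orm2 was 1.60 above (adjusted p = 0.0525, and 2.41 and past the threshold without slide 5). Within slides the Saa3 difference ran from -2.41 on slide 5 to 6.59. Without slide 5 it was 6.67 (adjusted p = 4.44e-07, with 4.44e-07 to 0.179 over all settings). The list mean was 1.11 (camera adjusted p = 4.41e-08, adjusted p = 0.167 with an estimated correlation) and 1.76 without slide 5, with 11 members higher over all genes.

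**Figure D2:**
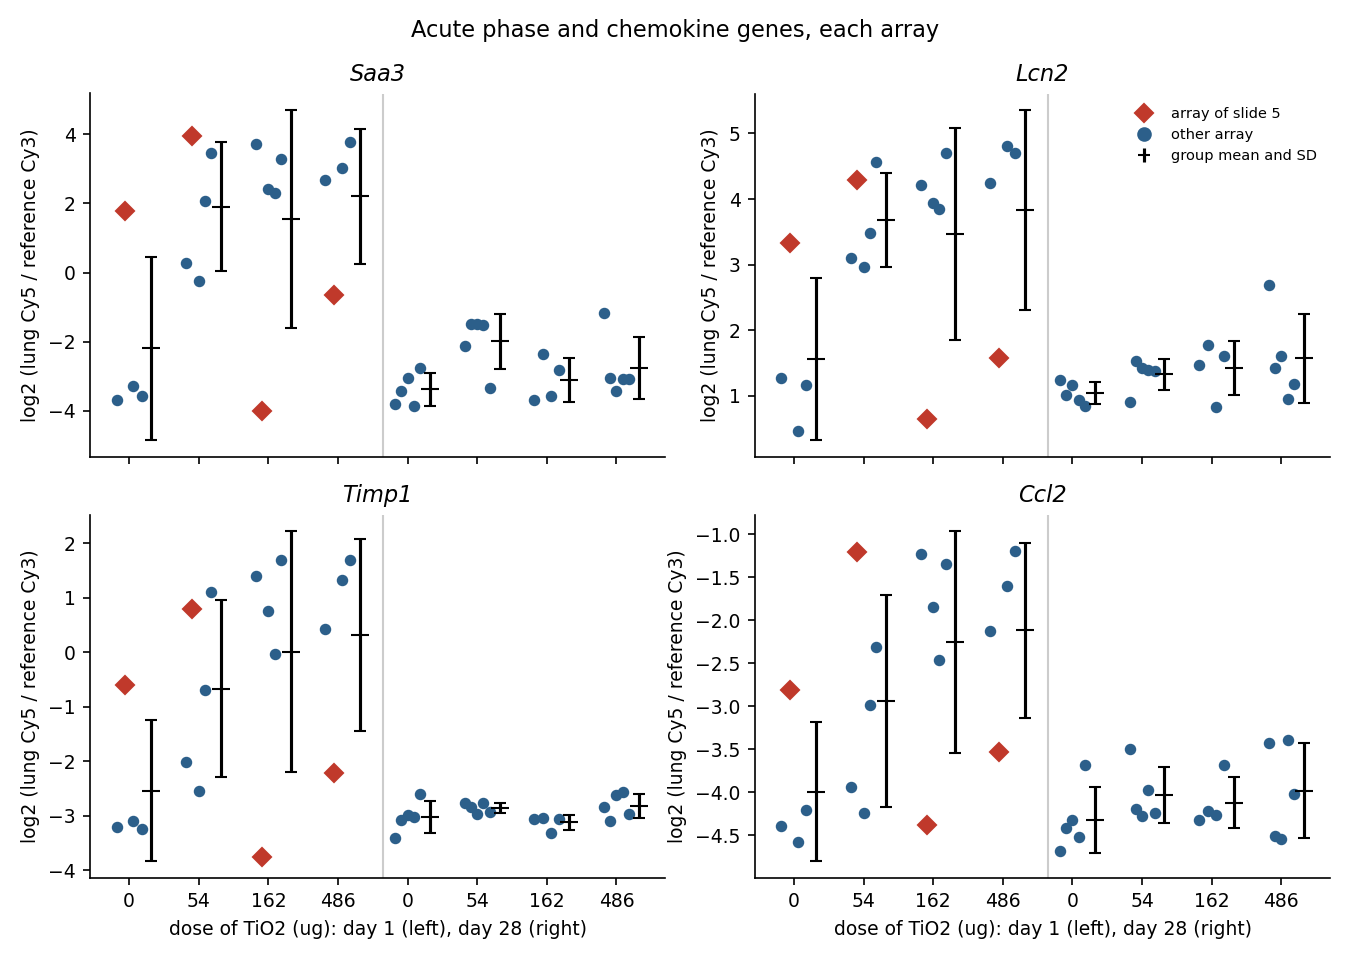
Log2 ratio to the reference of Saa3, Lcn2, Timp1 and Ccl2 on each array by dose, day 1 left and day 28 right, with group means and SD bars and the arrays of slide 5 as red diamonds. On slide 5 Saa3 is at 1.77 at 0 µg and -4.00 at 162 µg, against at most -3.27 and at least 2.30 on the other arrays of those groups.

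Chemokines lay on both sides of controls. Of 26 measured, 0 passed over all genes, and adjusted over the list alone 6 were higher and 4 lower (mean 0.32, camera adjusted p = 0.0189, adjusted p = 0.438 with an estimated correlation and 0.110 with slide as a block). Cxcl1, a neutrophil attractant, was 1.35 higher (adjusted p = 0.0571) and well above background on 2 of 4 control arrays, whereas Cxcl12, which retains leukocytes in tissue, was at -0.61 (adjusted p = 0.0525). The monocyte attractant Ccl2 was 1.88 ± 0.556 higher (adjusted p = 0.0642) and Ccl17, a T cell attractant, 1.27 (adjusted p = 0.0625), and without slide 5 these were 2.75 and 1.73, both past the threshold, as were Cxcl1 (1.57) and Cxcl12 (-0.75). Under scaling to equal spread Ccl2 came to 0.26, Ccl7 to 0.42 and Cxcl1 to 0.46, none past the threshold. Without slide 5, 8 chemokines were higher and 2 lower over all genes. Of 15 cytokines only Il6 passed, over all genes and over the list alone (mean 0.19, camera adjusted p = 0.0214, adjusted p = 0.302 with an estimated correlation), and the alarmin Il33 was at 0.85 (adjusted p = 0.130). Without slide 5, 4 cytokines were higher over all genes and 5 over the list alone, and Il33 was at 1.52 (adjusted p = 3.23e-06). Neutrophil markers gave no call over all genes, and 1 higher (Il1r2, 1.04) and 2 lower adjusted over the list alone (23 measured, mean 0.14, camera adjusted p = 0.0938), with Fpr1 at -0.78. Without slide 5 the neutrophil mean was 0.42 (camera adjusted p = 0.000859 at the preset correlation, the only one run there), with 3 members higher over all genes, and 8 higher and 2 lower over the list alone. Il1r2 was then at 1.66 (adjusted p = 7.41e-05). Macrophage markers (18 measured) had a mean of -0.11 and a median of -0.36 (camera adjusted p = 0.147), and the mean turned to 0.79 under scaling to equal spread and 0.021 with the background limited. Among them the growth factor receptor Csf1r fell by 0.60 and Adgre1, which encodes F4/80, was at -0.79 (adjusted p = 0.0542). Adjusted over the list alone, 1 macrophage marker was higher and 5 lower. Without slide 5 the mean was 0.047, Adgre1 passed (-0.96), and 2 macrophage markers were higher and 3 lower over all genes.

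Genes that glucocorticoids induce had the smallest camera p of the 40 lists at 486 µg on day 1 with all arrays and the preset correlation, whereas without slide 5 that of acute phase genes was smaller (adjusted p = 1.33e-16 against 2.24e-10). Of 13 measured, 3 rose over all genes, 10 adjusted over the list alone and 0 fell (mean 0.97, camera adjusted p = 1.03e-08, adjusted p = 0.130 with an estimated correlation). Fkbp5, a chaperone of the glucocorticoid receptor, rose 2.61-fold (1.39 ± 0.265, adjusted p = 0.0299), was higher on 3 of 3 slides, and was among the 5 genes kept with the background limited. Map3k6 and the cell cycle inhibitor Cdkn1a (1.38) were the other members past the threshold, and the pyruvate dehydrogenase kinase Pdk4 was at 1.32 (adjusted p = 0.0730). Without slide 5 Pdk4 passed (1.87), with 7 members higher over all genes. The list of p53 targets, which shares Cdkn1a, had 2 of 19 members higher over all genes and over the list alone (mean 0.18, camera adjusted p = 0.0189, adjusted p = 0.167 with an estimated correlation), the other being the stress cytokine Gdf15 (0.92). Under scaling to equal spread this list mean was 0.0056 (camera adjusted p = 0.899) and Gdf15 was at 0.23. Of 28 genes listed for oxidative stress or as targets of its regulator NRF2, 1 rose over all genes, the metallothionein Mt2. Adjusted over the list alone 6 rose and 1 fell (mean 0.19, camera adjusted p = 0.0207, adjusted p = 0.302 with an estimated correlation). The classic NRF2 targets Hmox1 (-0.80) and Nqo1 (-0.14) did not pass, nor did Mt1 (1.25, adjusted p = 0.0565, but -0.025 under scaling to equal spread). Without slide 5 Mt1 passed (1.73), and 6 members of the oxidative stress and NRF2 list were higher and 1 lower over all genes. Immediate early genes had 1 member higher over all genes, Myc (0.97, but -0.16 under scaling to equal spread). Their mean of 0.18 became -0.099 under that scaling (17 measured, 2 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00931, adjusted p = 0.326 with an estimated correlation).

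Genes of the extracellular matrix and of fibrosis rose in part. Of 38 measured, 3 rose over all genes, and 8 rose and 1 fell adjusted over the list alone (mean 0.23, camera adjusted p = 0.0189, adjusted p = 0.326 with an estimated correlation and 0.113 with slide as a block). Among these 3 were Tnc and the proteoglycan Vcan (0.71 ± 0.163, adjusted p = 0.0368). Timp1, an inhibitor of matrix proteases, was 2.85 ± 0.828 above controls (7.23-fold, adjusted p = 0.0610), with -1.62 on slide 5 and up to 4.58 on another slide, and 4.34 without slide 5. Thrombospondin 1 (Thbs1) was at 1.28 (adjusted p = 0.0620). Without slide 5 Timp1 and Thbs1 (1.78) passed, and 8 matrix genes were higher over all genes. The fibrillar collagens stayed near controls, with Col1a1 at 0.08 ± 0.239 (adjusted p = 0.893) and Col3a1 at -0.11, both of the other sign under scaling to equal spread, as did Fn1 (0.10, also turning), Tgfb1 (-0.043) and the myofibroblast actin Acta2 (0.38, adjusted p = 0.435). Among 18 matrix proteases and inhibitors 2 rose over all genes, the urokinase receptor Plaur (0.70) being one, and Mmp11 fell by 0.44, and adjusted over the list alone 6 rose and 1 fell (mean 0.39, camera adjusted p = 0.00370, adjusted p = 0.167 with an estimated correlation). Stromelysin Mmp3 (1.16, adjusted p = 0.0503) and Adamts4 (0.64, adjusted p = 0.0520) did not pass, but did without slide 5 (1.52 and 0.81), where 6 members of this list were higher and 3 lower over all genes. Cholesterol synthesis and uptake had 1 of 25 members higher over all genes, Pmvk, and 11 higher and 1 lower adjusted over the list alone (mean 0.32, camera adjusted p = 1.90e-07, adjusted p = 0.181 with an estimated correlation). Lanosterol synthase Lss was at 0.71 (adjusted p = 0.0503). Without slide 5 the mean was 0.48, 14 members were higher over all genes and 17 over the list alone, and Lss passed (0.91, adjusted p = 0.00367).

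Lists of interferon-induced genes and lymphocyte markers lay lower, with few members past the threshold and none of the 4 lists past it with an estimated correlation. Of 24 interferon response genes 1 fell over all genes, Gbp2, and 13 fell adjusted over the list alone (mean -0.47, camera adjusted p = 2.69e-06, adjusted p = 0.302 with an estimated correlation), with Gbp3 at -1.21 (adjusted p = 0.0610). Of 15 B cell markers 1 fell over all genes, the adaptor Blnk (-0.74 ± 0.164, adjusted p = 0.0368), and 5 adjusted over the list alone (mean -0.39, camera adjusted p = 0.000439, adjusted p = 0.302 with an estimated correlation), and Cxcr5 was at -0.68. T cell markers (13 measured, mean -0.34, camera adjusted p = 0.00270) and NK cell markers (12 measured, mean -0.51, camera adjusted p = 7.20e-05) gave 0 calls over all genes and 5 and 7 lower adjusted over the list alone, both with adjusted p = 0.302 with an estimated correlation. Their examples were Cd2 (-0.84, adjusted p = 0.0556), Cd3d (-0.72), Tbx21 (-0.81) and Nkg7 (-0.74), of which Cd3d and Nkg7 were at 0.13 and 0.20 under scaling to equal spread. All 4 of these lists were lower on 3 of 3 slides. Without slide 5, 8 interferon genes (Gbp3 among them, at -1.44), 2 B cell, 1 T cell and 0 NK cell markers were lower over all genes, and 13, 2, 5 and 0 over the list alone.

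Markers of airway and alveolar lining cells and of vessels were also lower in the ratios as normalized, but their direction turned when array ratios were scaled to equal spread. That scaling divides by each array's spread. On slide 5's 486 µg array the spread was 0.369, narrowed by the background fit, and 0.613 with the background limited. Scaling after limiting the background was not run. Ciliated cell genes had a mean of -0.61 (0.42 when scaled), club cell genes -0.43 (1.66), endothelial genes -0.43 (1.12) and alveolar type 1 genes -0.34 (1.13). These means stayed negative in every other setting run for lists, and without slide 5 were -0.59, -0.47, -0.28 and -0.29. With all arrays, 0, 0, 1 and 0 of their 16, 14, 20 and 13 measured members fell over all genes, and 8, 3, 7 and 3 adjusted over the list alone. Their camera adjusted p-values were 4.20e-06, 0.00679, 0.000345 and 0.00389, and with an estimated correlation they became adjusted p = 0.302, 0.326, 0.326 and 0.302. Among members that turned in the same way, ciliary Dnali1 was at -0.86 (adjusted p = 0.0690), Gabrp of the club cell list at -1.01 (adjusted p = 0.0563), the endothelial sialomucin Emcn at -0.76 and the alveolar type 1 marker Sema3e at -0.62 (adjusted p = 0.0563). The secretoglobin Scgb1a1 (-0.61, adjusted p = 0.111) and surfactant protein gene Sftpc (-0.84, adjusted p = 0.306) did not pass. The rest of the panel did not pass either with all arrays, with Saa1 at 2.38 (adjusted p = 0.0917), Lcn2 at 2.28 (0.0557), Ccl7 at 1.38, osteopontin Spp1 at 1.23 and Cxcl5 at 0.95. S100a8 was at 0.69, Gpnmb at 0.48, Tnf at 0.33, Il1b at 0.24, Arg1 at 0.14, Cxcl13 at 0.034, Retnla at -0.24 and Chil3 at -0.42. Of these, Sftpc, Scgb1a1, Spp1, Gpnmb, Retnla and Chil3 changed sign under scaling to equal spread. Without slide 5, Saa1 (3.75, adjusted p = 7.64e-05), Lcn2 (3.62, adjusted p = 4.44e-07), Ccl7 (2.03), Spp1 (2.08), Scgb1a1 (-0.99) and Sema3e (-0.60) passed. Ciliated, club, endothelial and alveolar type 1 genes then had 2, 3, 1 and 1 members lower over all genes.

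**Figure D3:**
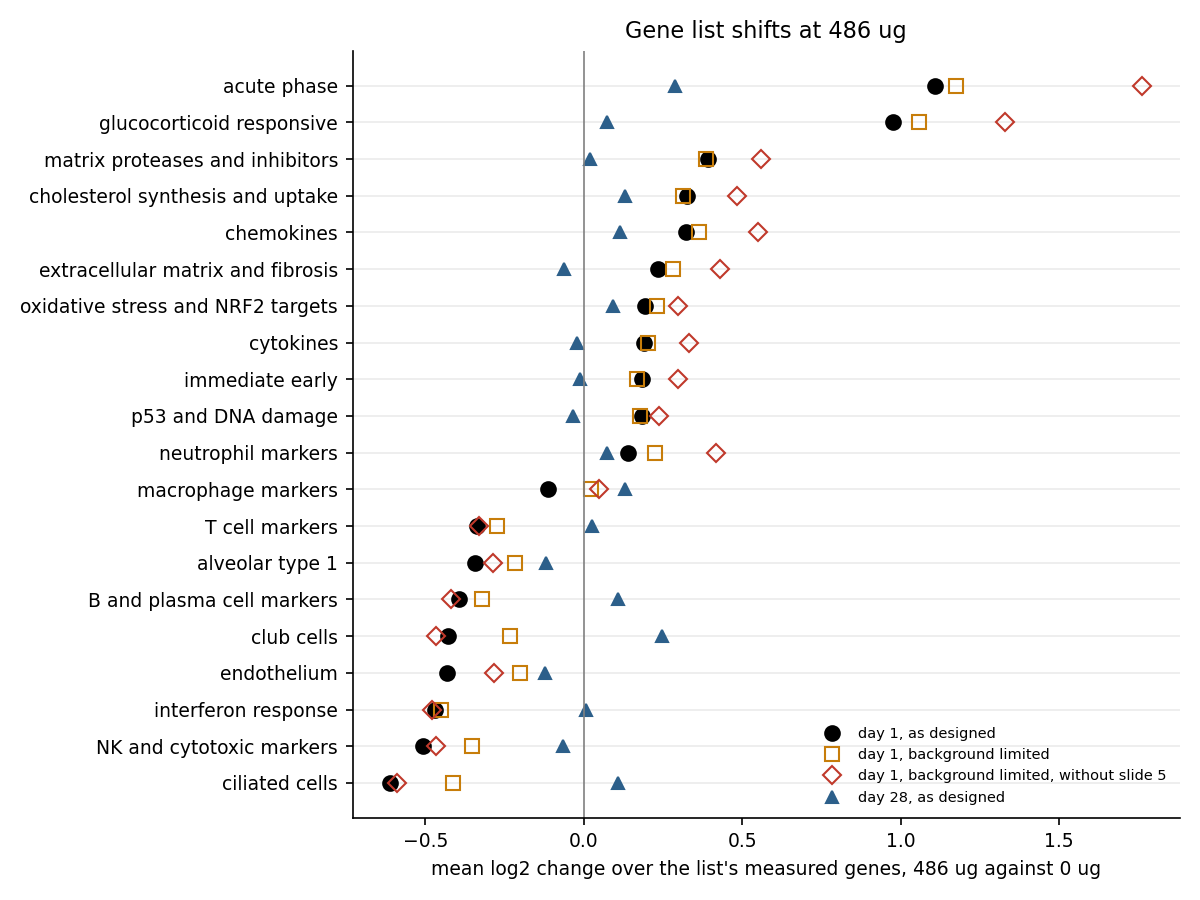
Mean log2 change of 20 gene lists at 486 µg against 0 µg, at day 1 as designed, with the background limited, and limited without slide 5, and at day 28. Acute phase genes lie at 1.11 at day 1 and 0.29 at day 28, and the negative means of ciliated, club, endothelial and alveolar type 1 genes at day 1 became positive (0.42, 1.66, 1.12 and 1.13) under scaling to equal spread, as did that of macrophage markers (0.79, and 0.021 with the background limited), while immediate early genes turned to -0.099. Without slide 5 the ciliated, club, endothelial and alveolar type 1 means stayed negative.

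At the lower doses on day 1, acute phase genes and chemokines stood above controls with no gene past the threshold. At 54 µg Saa3 was 4.10 ± 1.13 higher (SE, 5 against 4 arrays), with a mean of 1.90 ± 1.86 (SD) against -2.19 ± 2.65, and was higher on 4 of 4 slides. Lipocalin Lcn2 was 2.12 higher, Saa1 2.07, Timp1 1.87, the neutrophil attractant Cxcl5 1.84, Ccl17 1.1 and Ccl2 1.06. Limma called 0 genes at 54 µg, with 304 at an unadjusted p of 0.05 (1.42%, fewer than chance gives). The groups did not overlap for 115 genes (0.543% against 1.59% by chance). The acute phase list had a mean of 0.75 and 3 of 17 members higher adjusted over the list alone (camera adjusted p = 3.92e-10, adjusted p = 0.0967 with an estimated correlation). Chemokines had a mean of 0.45 and 2 of 26 members higher adjusted over the list alone (camera adjusted p = 1.02e-11, adjusted p = 0.0572 with an estimated correlation), both with 0 members over all genes. Skeletal muscle genes had a mean of 0.53 with 0 calls either way, adjusted over the list alone included (camera adjusted p = 3.97e-09, adjusted p = 0.0967 with an estimated correlation), with Acta1 at 1.29 and Ckm at 0.58, and the mean was 0.20 without slide 5. A single array stood apart on this list, 54 µg replicate 2 of slide 5 at 1.43, against -0.80 to 0.013 on the other 54 µg arrays. Without slide 5 Saa3 (4.91) and Lcn2 (2.56), both with adjusted p = 0.000127, and the Ly6 family gene Ly6f (1.40, chosen after its value was seen) passed at 54 µg, and adjusted over the list alone 6 acute phase genes and 12 chemokines were higher.

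At 162 µg on day 1, Saa3 was 3.74 ± 1.13 above controls, Timp1 2.56, Saa1 1.98, Lcn2 1.91, Ccl2 1.74, Ccl7 1.65 and Ccl12 1.00, with adjusted p from 0.445 for Ccl12 to 0.579. These genes were higher on 3 of 4 slides, slide 5 being the other. Limma called 0 genes, with 1673 at an unadjusted p of 0.05 (7.84%), and the groups did not overlap for 273 genes (1.29% against 1.59% by chance). Without slide 5 it called 468, 360 higher and 108 lower. Without 162 µg replicate 2 alone the count was 57. Saa3 was then 6.45 without the slide, Timp1 4.15, Saa1 3.41, Lcn2 3.20, Ccl2 2.67, Ccl7 2.62, Ccl17 1.77, Ccl12 1.37 and Cxcl1 1.16, all past the threshold. Acute phase genes had a mean of 0.84, with 0 over all genes and 2 adjusted over the list alone (camera adjusted p = 4.90e-07, adjusted p = 0.318 with an estimated correlation), and 9 higher over all genes without slide 5. Chemokines had a mean of 0.51, with 0 over all genes and 6 adjusted over the list alone (camera adjusted p = 4.90e-07, adjusted p = 0.302 with an estimated correlation), and 10 higher over all genes without slide 5.

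Set directly against 162 µg at day 1, 486 µg gave lower list means of interferon and T cell genes and a higher one of glucocorticoid-induced genes, with no gene past the threshold over all genes. On all 3 lists 162 µg replicate 5 (slide 9) stood apart from the other 162 µg arrays, with means of -0.32 against 0.55 to 0.94 for interferon, 0.083 against 0.40 to 0.57 for T cell and 1.95 against 0.81 to 1.5 for glucocorticoid-induced genes. Of 24 interferon response genes 14 were lower adjusted over the list alone (mean -0.53, camera adjusted p = 2.01e-10, adjusted p = 0.169 with an estimated correlation). Of 13 T cell markers 8 were lower adjusted over the list alone (mean -0.42, camera adjusted p = 3.48e-07, adjusted p = 0.150 with an estimated correlation). Of 13 glucocorticoid-induced genes 6 were higher adjusted over the list alone (mean 0.60, camera adjusted p = 1.10e-07, adjusted p = 0.150 with an estimated correlation). Over all genes limma called 0, in these lists and elsewhere, with 2641 at an unadjusted p of 0.05 (12.4%). The count was 55 without slide 5, 657 without 162 µg replicate 5, 89 without 486 µg replicate 2 and 84 with slide as a random block (8 higher, 76 lower).

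At day 28 lungs given 486 µg had 2 genes past the threshold against controls. The inflammatory and matrix genes named in this paragraph lay nearer controls than at day 1, though the acute phase list mean did not overlap between the groups. Dbp, an output gene of the circadian clock, rose 5.19-fold (2.38 ± 0.387, SE, 5 against 5 arrays, adjusted p = 0.0135), from -1.28 ± 0.501 to 1.1 ± 0.567 (SD). Serpina1d, an alpha-1 antitrypsin gene of hepatocytes, rose 3.18-fold (1.67 ± 0.291, adjusted p = 0.0220), from 0.073 ± 0.127 to 1.74 ± 0.742. Both were higher on 5 of 5 slides, by 1.62 to 2.96 and 0.86 to 2.34, and passed with slide as a block. Saa3 was at 0.61 ± 1.07, Lcn2 at 0.53, Ccl2 at 0.34, Timp1 at 0.21 (-0.022 under scaling to equal spread) and Col1a1 at -0.050 ± 0.214, each with an adjusted p of 1.00.

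At an unadjusted p of 0.05 that comparison held 578 genes (2.71%, fewer than chance gives), and its groups did not overlap for 161 (0.755% against 0.794% by chance). With slide as a fixed block limma called 14 genes (11 higher, 3 lower), with a random block 16 (11 and 5) and with scan day as a block 13 (11 and 2). Dbp lost its call without 0 µg replicate 1, 2 or 5 or 486 µg replicate 4 or 5, with an adjusted p of up to 0.107, and Serpina1d without any single 0 µg array or 486 µg replicate 3, 4 or 5, with up to 0.204, and 0.190 in a model of only those groups. Both genes' adjusted p ran from 0.00176 to 0.107 and from 0.000189 to 0.204 over all settings. Without 486 µg replicate 1 the count was 11 and without replicate 2 it was 8. It was 1 without 0 µg replicate 3 or 4 or 486 µg replicate 3, and 0 without the other 5. Other hepatocyte genes moved with Serpina1d. Of 25 measured from a list of 29 written after its value was seen, 15 were higher adjusted over that list and 0 over all genes, with albumin Alb at 1.60 (adjusted p = 0.0927).

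Clock genes of opposite phase moved apart at 486 µg on day 28. Of 17 measured, 1 rose over all genes, Dbp, and adjusted over the list alone 5 were higher and 4 lower (mean 0.31, camera adjusted p = 0.00405, adjusted p = 0.293 with an estimated correlation). The nuclear receptor Nr1d2 was at 0.94 ± 0.200 (adjusted p = 0.111) and the clock activator Arntl at -0.89 ± 0.197 (adjusted p = 0.126, and 0.0401 without the day 1 arrays of slide 5). Heat shock genes were all 12 below 0, with 0 calls over all genes or adjusted over the list alone (mean -0.25, camera adjusted p = 1.14e-05, adjusted p = 0.293 with an estimated correlation), led by Hspa1a (-0.70) and Hsph1 (-0.48). Acute phase genes had a mean of 0.29, 0 members past over all genes and 1 adjusted over the list alone (camera adjusted p = 0.000556, adjusted p = 0.578 with an estimated correlation). That member was fibrinogen Fgb (1.05, adjusted p = 0.126), itself a hepatocyte gene and well above background on 1 of 5 control arrays. The acute phase mean was 0.537 to 0.770 on the 486 µg arrays and 0.261 to 0.521 on controls, a separation looked for after the values were seen. The estimated correlation also rests on the day 1 arrays of slide 5, which are not in this comparison. Cholesterol genes had a mean of 0.13 (camera adjusted p = 0.000136, adjusted p = 0.578 with an estimated correlation) and matrix genes -0.06 (0.0276, adjusted p = 0.745 with an estimated correlation), each with 0 calls over all genes or adjusted over the list alone. Fdft1 was at 0.32 and Itgb6 at -0.42. Chemokines (mean 0.12) and macrophage markers (0.13) had a camera adjusted p of 0.174 and 0 calls either way. Of the panel, Retnla was at 0.69, Spp1 at 0.50, Gpnmb at 0.48, Acta2 at 0.33, Cxcl1 at 0.32 and Hmox1 at 0.26, all with an adjusted p of 1.00.

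**Figure D4:**
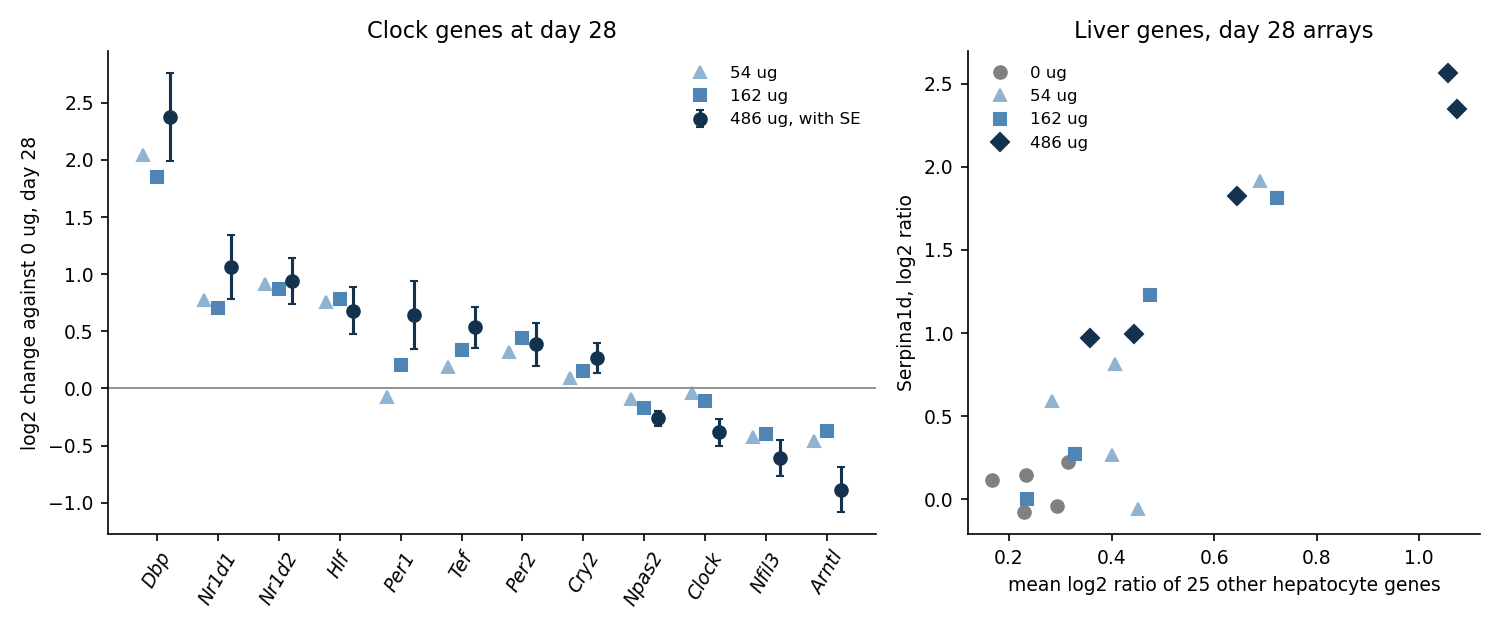
Left, log2 change of clock genes at day 28 for 54, 162 and 486 µg against 0 µg, with the SE at 486 µg. Right, the log2 ratio of Serpina1d against the mean of 25 other hepatocyte genes on each day 28 array by dose, where the 486 µg arrays reach 2.57 for Serpina1d and controls stay at or below 0.22.

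At 54 and 162 µg on day 28 no gene passed, and genes of heart muscle, fat and mucous airway cells stood above controls. At 54 µg, where the counts were 0 by limma and 1718 at an unadjusted p of 0.05 (8.05%), the groups did not overlap for 311 genes (1.46% against 0.794% by chance). Dbp was 2.04 ± 0.387 higher (adjusted p = 0.0866) and Nr1d2 0.92. Cardiac muscle genes had a mean of 1.28 and 12 of 16 members higher adjusted over the list alone (camera adjusted p = 2.44e-09, adjusted p = 0.273 with an estimated correlation), among them the calcium channel Ryr2 (0.45) and troponin Tnnc1 (1.31). Adipose genes had a mean of 1.25 and 7 of 11 higher (2.13e-07, adjusted p = 0.225 with an estimated correlation), with the fatty acid carrier Fabp4 at 2.17. Goblet cell genes had a mean of 1.16 and 6 of 14 higher (2.80e-07, adjusted p = 0.273 with an estimated correlation), with trefoil factor Tff2 at 1.90. B cell markers had a mean of 0.32 and 6 of 15 higher (2.94e-07, adjusted p = 0.225 with an estimated correlation), with Blnk at 0.61. Clock genes had a mean of 0.27, with 4 higher and 1 lower (0.0166, adjusted p = 0.273 with an estimated correlation). All these list counts are adjusted over the list alone, and 0 members passed over all genes. With array weights limma called 545 genes at 54 µg, with slide as a random block 7 and with scan day as a block 4, and 30 without 54 µg replicate 5 and 1 without replicate 1.

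At 162 µg on day 28 limma again called 0 genes, with 481 at an unadjusted p of 0.05 (2.25%, fewer than chance gives). The groups did not overlap for 342 genes (1.60% against 1.59% by chance). Cardiac genes had a mean of 0.98 (camera adjusted p = 8.14e-08, adjusted p = 0.713 with an estimated correlation), adipose genes 0.63 (0.00477, adjusted p = 0.713 with an estimated correlation) and goblet genes 0.54 (0.0240, adjusted p = 0.714 with an estimated correlation), with 0 calls adjusted over the list alone. The goblet mean was 0.32 without 162 µg replicate 4 (camera adjusted p = 0.428) and 0.17 with the scanner's ratio, and its list test was lost in 10 of 30 other settings. Sarcolipin Sln was at 2.29, Tnni3 at 1.45, adipsin Cfd at 1.42 and the airway secretory gene Bpifa1 at 1.90, each with an SE of at least 0.744. Clock genes had a mean of 0.28 and 3 higher adjusted over the list alone (0.00477, adjusted p = 0.587 with an estimated correlation), with Dbp at 1.85 ± 0.410 and Nr1d2 at 0.87. At 486 µg the same cardiac, adipose and goblet lists had means of 0.50, 0.65 and 0.48 (camera adjusted p = 0.00401, 0.000940 and 0.0247, adjusted p = 0.826, 0.578 and 0.826 with an estimated correlation), with Plin1 at 1.1, Fabp4 at 1.20 and Muc5b at 1.03 and 0 calls adjusted over the list alone. Without 486 µg replicate 5, whose cardiac and adipose means were 2.83 and 4.27, these means were 0.19, 0.26 and 0.35, none past the threshold (camera adjusted p = 0.453, 0.327 and 0.198). Between 486 and 162 µg at day 28 limma called 0 genes, with 660 at an unadjusted p of 0.05 (3.09%, fewer than chance gives). In that comparison acute phase genes had a mean of 0.21 (camera adjusted p = 0.0162, adjusted p = 0.995 with an estimated correlation) with 0 calls adjusted over the list alone.

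The change of effect between days was tested directly. For 486 µg the acute phase mean was 0.82 lower at day 28 than at day 1 (camera adjusted p = 0.00104, adjusted p = 0.384 with an estimated correlation), and the glucocorticoid-induced mean 0.90 lower (7.38e-07, adjusted p = 0.183 with an estimated correlation). Interferon response genes were 0.48 higher at day 28 than at day 1 relative to controls (6.17e-06, adjusted p = 0.362 with an estimated correlation). For 162 µg the acute phase mean was 0.76 lower (0.000128, adjusted p = 0.511 with an estimated correlation). Limma called 0 genes in either test of the difference. At an unadjusted p of 0.05 there were 2148 genes for 486 µg (10.1%) and 847 for 162 µg (3.97%, fewer than chance gives). Without slide 5 it called 506 genes for 486 µg (135 higher, 371 lower) and 40 for 162 µg, with array weights 404 for 486 µg, and without 486 µg replicate 2 of day 1 it called 117.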

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

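All tests of slide 5, of hepatocyte genes and of the clock were chosen only after the result was seen, whereas the counts over other splits of the arrays were planned. An array far from the rest of its group was looked for in 210 combinations of a group with a named gene or list, and 15 were found (7.14%, against about 1 in 20 by chance, 5%). Of these, 7 lay on slide 5. On its control array (replicate 2) Saa3 was at 1.77 and Timp1 at -0.59, against at most -3.27 and -3.10 on the others, and the glucocorticoid-induced and cholesterol list means were at 1.03 and -0.14, against at most 0.78 and -0.31. On its 486 µg array (replicate 2) Pla1a was at -0.55 and the NRF2 list mean at 0.030, against at least 1.40 and 0.44 on the others, and Scgb1a1 was at 6.96, against at most 6.17. Elsewhere at day 1, Pmvk was at -0.32 on 0 µg replicate 1 and Retnla at 6.60 on 0 µg replicate 3. At day 28, Col1a1 was at -1.02 on 0 µg replicate 5, the cholesterol list mean at -0.33 on 0 µg replicate 2 and the macrophage list mean at 2.50 on 0 µg replicate 3. Among 486 µg arrays of that day, Saa3 was at -1.17 and the cholesterol list mean at -0.27 on replicate 1 and Fn1 at -2.53 on replicate 3.

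The arrays of slide 5 stood out of dose order. On a scale of the genes that separated 486 µg from control arrays, with 0 at the mean of the controls and 1 at that of the 486 µg arrays of the other slides, its 0, 54, 162 and 486 µg arrays lay at 0.406, 0.805, -0.059 and 0.152. Its control array lay within the range of the other controls, 0.044 to 0.416, which were placed on scales that held slide 5. With the background limited it lay at 0.406, above the other controls at 0.099 to 0.296. An exchange of the 0 and 162 µg labels alone would leave the 486 µg array near 1, yet it lay at 0.152, where the others lay between 0.836 and 1.03. One array of another slide also stood out, 162 µg replicate 5 of slide 9, at 1.01, where the other 162 µg arrays lay at -0.059 to 0.367. A shift common to the slide would move its 4 arrays one way, but their acute phase means departed from their groups by -1.57 to 1.04, where the median SD of the other arrays was 0.273. The 24 orders of the slide's labels were tried on this scale and on that of 162 µg. At most 2 of the 4 arrays fell within the range of their new group on both, and 0 as labelled. This cannot decide on misplaced labels, because the ranges came from scales that held slide 5. On that of 162 µg the other controls lay at 0.357 to 0.472, above 162 µg replicate 1 at 0.166. Each range also rests on 3 or 4 other arrays, and the upper end of that of 162 µg on the first scale is the array of slide 9. Exchanging 0 with 162 µg and 54 with 486 µg was looked at after the values were seen. Acute phase means by new dose were then 0.315, 0.651, 1.502 and 1.96, below the lowest others at 0.359, 0.993, 1.51 and 1.976. Misplaced labels may still have a part and stay open. A difference in how single mice took up the dose was not tested.

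Serpina1d, which rose at 486 µg on day 28, moved with other hepatocyte genes. Over the 19 arrays of that day, with group means removed, it correlated with the mean of 25 others at r = 0.850 (permutation p = 1e-05, the smallest these permutations can give) and rho = 0.802 (permutation p = 0.00011), with r = 0.813 without the 2 arrays farthest from the median and 0.727 with slide means removed as well. A rise of Serpina1d alone in the lung is argued against by the 15 other hepatocyte genes that were higher adjusted over the list alone, with all 25 above 0 (mean 0.47, higher on 5 of 5 slides). RNA from liver tissue in some samples is consistent with the r of 0.850, and liver was taken from the same mice per the labels. A lung response of many hepatocyte genes was not tested apart from it, so a biological source stays open as well.

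The clock genes of dosed lungs at day 28 differed from controls in phase. The mean of 5 genes of the phase of Dbp (Dbp, Tef, Nr1d1, Nr1d2, Per3) minus that of 3 of the opposite phase (Arntl, Npas2, Clock) was 1.52 higher at 486 µg than at 0 µg, 1.00 higher at 54 µg and 0.97 higher at 162 µg (exact permutation p = 0.00794, 0.00794 and 0.0238, adjusted p = 0.0238, 0.0238 and 0.0476 over 6 tests). This score holds Dbp, whose call prompted it, so its p partly restates that call. Without Dbp the differences were 1.18, 0.69 and 0.70 (exact permutation p = 0.00794, 0.00794 and 0.0317, adjusted p = 0.0119, 0.0119 and 0.0317 over 3 tests), for genes whose values had also been seen. At day 1 the differences with Dbp were 0.083, 0.15 and 0.23 at 54, 162 and 486 µg (exact permutation p = 0.833, 0.651 and 0.486). Slide is argued against at 486 and 54 µg, where the dosed array lay above the control array on 5 of 5 slides, but less so at 162 µg, where it did on 3 of 4 (lowest difference -0.21). Collection of the controls at another time of day than dosed mice is consistent with the exact p of 0.00794 at 486 µg with Dbp left out, but stays open, and a lasting effect of the particles on the clock, which the design could also give, was not tested.

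Counts of genes past the threshold were set against other splits of the same arrays into groups of the same sizes, which took no account of slide, and exchanges within slides alone were not counted. For 486 against 0 µg at day 1, 2 of the 35 splits gave as many genes as the 310 of the real one, so chance cannot be excluded, and with slide as a fixed block the real count was 0. The highest other split gave 780 and exchanged the 0 and 486 µg arrays of slide 5, which points to that slide's place in the data, and a split by scan day gave 0. For 486 against 0 µg at day 28, 1 of 100 splits, the real one, gave 2 genes and the highest other gave 1. The 100 were taken from 126 possible splits, in a model without slide, and this was 1 of 10 comparisons so tested. Chance is therefore not excluded. The margin was 1 gene, and the count was 0 or 1 when any of 8 of the 10 arrays was left out. In the other comparisons 0 genes passed, a count that all 100 splits reach by definition, so the splits say nothing about chance there. Their highest other splits gave 106 genes at 54 µg and 865 at 162 µg on day 1, and 7 and 0 at day 28. They gave 2265 and 14 for 486 against 162 µg at day 1 and day 28, and 5 and 1 for the differences between days at 162 and 486 µg. The 865 and 2265 point to a structure of the day 1 arrays other than their labels.

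In 22 pairs of a dose and a list described above the effect differed between days by camera with a preset correlation. None did with an estimated one (adjusted p from 0.156 to 0.713). Lists not described above were not counted, and acute phase and goblet genes appear at both doses. Given as the effect at day 28 minus that at day 1, those at 162 µg were acute phase -0.76, chemokines -0.50, goblet cells 1.22, cardiac muscle 1.56 and adipose 0.93. At 486 µg the immune lists were acute phase -0.82, cytokines -0.21, macrophage 0.24, B cell 0.50, T cell 0.36, NK cell 0.44 and interferon response 0.48. Those of matrix and stress were extracellular matrix -0.30, matrix proteases -0.37, cholesterol -0.195, p53 targets -0.22, heat shock -0.35, immediate early -0.195 and glucocorticoid-induced genes -0.90. Those of the airway were club 0.68, goblet 1.02 and ciliated cells 0.72.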

How the results depend on the processing

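The settings that limit the background, and those that leave out slide 5, its 0 and 162 µg arrays or the 3 arrays the scanner software marked, and the block of replicate number were chosen after seeing the data. Of counts of genes under other settings, 265 stayed within 1.5 times of the reported one and 74 did not. Of values of named genes 4337 kept their side of the threshold, 446 lost the call and 267 gained one. A further 2 changed sign with a call in either setting, and of gene lists the counts were 1301, 114, 14 and 6. Values that changed sign without a call in either setting are among those that kept their side. So are genes and lists with no call as designed that stayed without one, and a count of 0 that stayed 0 is among the unchanged counts. These totals therefore overstate how well calls held. For 486 against 0 µg at day 1 (310 genes) the count was 0 with slide as a fixed block, the scanner's ratio, or without the marked arrays. It was 5 each with no background correction, the series table and the background limited, 10 under scaling to equal spread, 57 in a model of only those groups, 85 with Cy5 alone, 112 with no filter on dim probes, 705 with slide as a random block and 2678 with array weights. For 486 against 0 µg at day 28 (2 genes) it was 5 each with the series table, scaling, the background limited and without the marked arrays, 6 with the scanner's ratio, 7 with array weights, 10 with Cy5 alone, 13 with scan day as a block, 14 with slide fixed and 16 with slide random. For 54 µg at day 28 it was 2 in a model of only those groups, 4 with scan day as a block, 7 with slide random and 545 with array weights, against 0. For 486 against 162 µg at day 1 it was 84 with slide random and 1036 with array weights, and for the 486 µg difference between days 404 with array weights, against 0 in both. Without slide 5 the counts at day 1 were 3, 468 and 1998 in order of dose, 8 for 486 µg at day 28, 55 for 486 against 162 µg at day 1, and 40 and 506 for the differences between days. With the background limited too they were 2, 476, 2032, 8, 54, 39 and 568. Without only its 0 and 162 µg arrays they were 3 and 116 at 54 and 162 µg, 6 for 486 µg at day 28 and 2 for the 162 µg difference between days.

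Leaving out 1 array at a time gave 0 to 57 genes for 162 µg at day 1 (57 without 162 µg replicate 2), 0 to 1613 for 486 µg at day 1 (1613 without 486 µg replicate 2), 0 to 30 for 54 µg at day 28 (30 without 54 µg replicate 5) and 0 to 11 for 486 µg at day 28 (11 without 486 µg replicate 1). For 486 against 162 µg at day 1 it gave 0 to 657 (657 without 162 µg replicate 5), for the 486 µg difference between days 0 to 117 (117 without 486 µg replicate 2 of day 1), and for the others 0. Under scaling to equal spread the alveolar type 1 mean at 486 µg on day 1 reversed to 1.13, ciliated to 0.42, club to 1.66, endothelium to 1.12, macrophage to 0.79 and immediate early to -0.099, and Gbp2 to 0.040 and Myc to -0.16. Scaling divides by each array's spread, which was 0.369 (median absolute deviation) on slide 5's 486 µg array and at least 0.532 on all but 2 others (0.455 and 0.497). Limiting the background of 39 spots brought these 3 arrays to 0.613, 0.597 and 0.592. In those arrays the fitted SD of the background had been 134 and 57.3 in Cy3 and 66.2 in Cy5, against medians of 1.30 and 1.54, so the fit on a few spots narrowed their ratios. Of the 310 genes, 279 (90%) moved against the sign of their mean ratio, as 67.3% of all genes did, and their median adjusted p became 0.105 with the background limited. For the other settings the cause was not tested. Replicate numbers follow deposit order, and 34 of the 52 pairs of arrays with the same number and day lay on 1 slide. With group means removed, the closest array of another group had the same number for 18 of 37 arrays and lay on the same slide for 26, and same-numbered arrays correlated at -0.249 to 0.649. With the replicate number as a replicate block, 897 genes passed for 486 against 0 µg at day 1, 6 for 486 µg at day 28, 288 for 486 against 162 µg at day 1 and 0 elsewhere, where slide as a fixed block gave 0, 14 and 0. The median lung signal of an array stood at most 2.15 times above background, so changes of dim genes such as Il6 and Fgb are the least certain in size.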

Other observations

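Other lists at day 1 had a camera adjusted p under the threshold with the preset correlation and not with an estimated one. At 486 µg genes of the unfolded protein response had a mean of 0.20 and cell cycle genes 0.16 (20 and 32 measured, 0 calls over all genes or adjusted over the list alone, camera adjusted p = 0.00137 and 0.0106, adjusted p = 0.302 and 0.577 with an estimated correlation). Alveolar type 2 and surfactant genes had a mean of -0.19 and a median of -0.34, with 1 of 20 lower over all genes and 2 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.0209, adjusted p = 0.438 with an estimated correlation). At 54 µg alveolar type 1 genes had a mean of -0.21 and endothelial genes -0.18 (camera adjusted p = 6.92e-05 and 0.000209, adjusted p = 0.255 and 0.574 with an estimated correlation), with 0 calls over all genes or adjusted over the list alone. At day 28 lists of the vessel and alveolar wall lay below controls at 54 µg, endothelium at -0.26 and alveolar type 1 at -0.29 (camera adjusted p = 1.77e-06 and 1.01e-05, adjusted p = 0.338 and 0.225 with an estimated correlation). Both were lower on 5 of 5 slides, with 0 calls over all genes and 0 and 2 lower adjusted over the list alone. Heat shock genes were at -0.21 and -0.16 at 54 and 162 µg on day 28, each with 12 of 12 members below 0 and 0 calls adjusted over the list alone (camera adjusted p = 0.000118 and 0.00477, adjusted p = 0.273 and 0.713 with an estimated correlation).

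Genes of heart muscle, fat and mucous airway cells varied together between lungs of the same group. Over 37 arrays with group means removed, the cardiac list mean correlated with the adipose mean at r = 0.841 and rho = 0.841 (permutation p = 1e-05 for both, the smallest these permutations can give, adjusted p = 2e-05 and 4e-05 over 4 relations). It correlated with the goblet cell mean at r = 0.826 and rho = 0.766 (permutation p = 1e-05 and 3e-05, adjusted p = 2e-05 and 6e-05). Without the 2 arrays farthest from the median these were r = 0.836 and 0.769, and with slide means removed as well 0.705 and 0.731. The cardiac mean did not follow the alveolar type 1 mean (r = -0.127, rho = -0.074, permutation p = 0.51 and 0.70) or the endothelial mean (r = -0.074, rho = -0.114, permutation p = 0.71 and 0.53). The labels describe randomly taken sections of lung.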
